A study of Schizosaccharomyces pombe with 56 samples.

How the data were processed

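Chromatin was immunoprecipitated from cross-linked fission yeast cells before and after transfer to medium without nitrogen, and sequenced with matched inputs for part of the libraries, per the labels' protocols. The authors' processing used Bowtie2 2.2.7, MACS2 2.1, DiffBind 1.16.3 and DESeq2 with genome build ASM294v2, per the submitters' processing notes, which give these names without role or order. Bowtie2 is an aligner, MACS2 a peak caller, and DiffBind a package that counts reads in peaks and compares groups. Whether input reads were subtracted, how regions were merged and which filters were applied are not given in the sources used here. The labels list an input for wild-type H3K9me2 replicates 1, 2, 5 and 6, and the sheet name of the tables gives the digits 1, 3, 4, 5 and 6.

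Per the file headers, the authors deposited log2 values, namely the mean normalised reads per region over both groups and for wild type at 0 h and 24 h, and the log2 fold as 0 h minus 24 h. Here the sign was turned, so that a positive log2 change is higher at 24 h. The authors deposited a p-value and an FDR per region, per the file headers. The deposited FDR equalled the Benjamini-Hochberg adjustment over the 1385 regions listed below 1, with a largest difference of 1.5e-15, so the other 807 regions took no part in it. Those regions were listed with a p of 1. The deposited group means never fell below 0.77 normalised reads, at which 1154 regions stood at 0 h and 151 at 24 h.

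The design fixed beforehand allowed for counts or normalised values per library. Since the tables hold group means, the authors' own folds and FDR were described in their place, with an FDR of 0.05 as threshold. Values are the authors' means, so no SD or n stands beside them. The depth per library is not given in the tables, and it limits the low values most, since the minimum is about 1 read per library. Folds against a group at its minimum were bounded with 3 counts per library at the table's scaling (2.31 normalised reads in either group). The 3 counts are a choice made here. If input reads were subtracted, more reads may have lain behind a minimum. Folds given as at least a value are therefore bounds on the deposited values and not on H3K9me2 itself. Intervals cover counting error only. Nothing in the labels says whether replicates came from separate cultures, so p-values of tests between libraries measure the spread between these libraries, which may be technical. Fisher's exact tests and permutation tests over genes or regions hold no spread between libraries. Genes and regions share the same libraries and are not independent replicates, so those p-values describe the table.

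The group means were also decomposed into whole counts per library. The differences between the smallest means gave the weight of 1 read in each library with signal, 2 libraries at 0 h and 3 at 24 h, and each mean was then searched for whole counts above the minimum at these weights, up to 600 normalised reads and within a relative tolerance of 3e-14. The recovery assumes 5 libraries per group, as the digits in the sheet name list, and every count given out of 5 libraries rests on this. Under it, 3 libraries at 0 h and 2 at 24 h stood at their minimum in the resolved regions. At 0 h 2177 of 2192 regions were resolved and at 24 h 2175, each with 1 solution, and of 1026 and 2029 shifted values 0 were resolved. On 1000 simulated regions per group the counts were recovered for 100%. The heterochromatin domains lay above the limit. A few regions below it, tef102 and the tRNA genes beside centromere II among them, had no solution, and reads in the remaining libraries are not excluded there. limma 3.58.1 (R 4.3.3) with a mean trend was fitted to log2(value + 1) of the recovered values of 2174 regions, and the Benjamini-Hochberg adjustment was used. This fit sets the libraries without recovered signal to 0, and a fold is on the log2(value + 1) scale, which understates changes of low regions. On simulated counts for 2174 regions it recovered 38% of 2-fold, 96% of 4-fold and 100% of 8-fold changes, with 5 false calls. The simulation drew reads for all 5 libraries of each group and entered none as 0. Its shares therefore do not tell how many changes the fit could find in the recovered values.

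Gene names and overlaps came from the RefSeq annotation of ASM294v3. Its nuclear chromosome lengths equalled the last region ends of the deposited table on all 3 chromosomes, and coordinates printed are those of the deposited table, counted from 1. Regions were assigned to each annotated gene they overlapped by at least 1 bp. Gene lists (18, with 236 of 238 listed symbols matched, or patterns of gene names and gene classes) and heterochromatin windows were fixed before the data were examined: the 3 centromeres, the mating-type locus, 50 kb at each end of chromosomes I and II and 30 kb at each end of chromosome III. Lists were tested by Fisher's exact test, two-sided, against other annotated genes of the same kind, with Benjamini-Hochberg adjustment over 18 lists, and also against genes under tested regions, an alternative chosen after the data were seen. The recovery of counts, limma, the adjustment over all listed regions, the widest-region comparison and the counts without single libraries were likewise chosen then. The gene zym1, which encodes a metallothionein, was put in the sugar list by mistake and was left there. On simulated lists of 30 genes, 12 of them drawn from the 535 genes under increased regions, all 100 were found, and 3 of 100 random lists had a p under 0.05. Members adjusted over the list alone used the smallest region p of each member.

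Named regions followed a rule fixed beforehand: the 10 largest increases and 10 largest decreases past the threshold, the 5 smallest p in each direction, and up to 3 members with the smallest p in each list. Further list members are named as examples and were chosen after their values were seen. Permutation tests used 100000 resamples with a fixed seed and were two-sided. Codon adaptation was computed from annotated coding sequences of at least 50 codons, with the ribosomal protein genes as reference set. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Alternatives covered the FDR, a minimum fold, merging of regions within 500 bp, a minimum mean of 10, window sizes, overlap rules, scaling to the same total or median, and the recovered libraries left out in turn.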

Results

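Dimethylation of histone H3 at lysine 9 (H3K9me2), the modification that marks silent heterochromatin in fission yeast (Schizosaccharomyces pombe), was profiled by ChIP-seq in cells entering quiescence, the resting state reached when growing cells are moved to medium without nitrogen. The series holds 56 libraries, of which 24 were H3K9me2 immunoprecipitations, 6 were H3K9me3 immunoprecipitations and 26 were inputs. Wild type was sampled before starvation (0 h) and after 1 h and 24 h, with 6, 2 and 6 H3K9me2 libraries. Strains lacking clr4, which encodes the H3K9 methyltransferase, or ago1, which encodes the Argonaute protein of RNA interference, had 2 H3K9me2 libraries per time point, at 0, 1 and 24 h for clr4D and at 0 and 24 h for ago1D. The tables examined here hold the comparison of wild type at 24 h with 0 h, as 1 mean per group and region, and give no depth and no spread for any library. The 1 h, clr4D, ago1D and H3K9me3 libraries were not analysed here.

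The comparison of 24 h with 0 h asked where H3K9me2 was gained or lost in quiescent wild-type cells. In the authors' deposited table H3K9me2 was higher at 24 h at many sites along the chromosome arms: 453 of the 2192 regions were higher at 24 h and 10 were lower at an FDR of 0.05, so that 97.8% of the 463 changed regions rose (exact binomial 95% interval 96.1% to 99.0%). This interval treats regions as independent, although they share the same libraries. The share is also tilted by the minimum, at which 1154 regions stood at 0 h and could not fall, against 151 at 24 h. The increased regions overlapped 535 protein-coding genes, among them those of the plasma membrane proton pump (pma1), of translation elongation factors (tef3 and tef102) and of pyruvate kinase (pyk1). The broad domains at the centromeres, the mating-type locus and the chromosome ends had the highest levels at both times, and none of them passed the threshold. At 0 h 400 of the 453 increased regions stood at the lowest value of the table, 0.77 normalised reads, so their folds are given as lower bounds against 3 counts per library, which is 2.31 normalised reads on the table's scale. These bounds hold for the deposited values only, since a region at the minimum may have held more reads if input reads were subtracted beforehand.

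The increases were large where they occurred. The median log2 change of the 453 increased regions was 4.75 in the authors' deposited table, with a range of 2.90 to 9.11, and their median level at 24 h was 24.3 normalised reads. For the 400 at the 0 h minimum these log2 changes are against 0.77 normalised reads. They therefore exceed the lower bounds given for single regions. They covered 683 kb, or 5.41% of the genome, and were spread over chromosomes I, II and III at 34.6, 35.9 and 38.7 regions per Mb. The share of tested regions that rose did not differ detectably between chromosomes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p of 0.225, 0.858 and 0.225 over 3 tests). A further 807 regions were listed in the authors' deposited table with a p of 1, and 665 of them had a log2 change of 1 or more. Whole counts recovered from the group means, within a relative tolerance of 3e-14, gave signal in 2 or 3 of the 5 libraries assumed at 24 h for each increased region with a recovered make-up, 451 of 453, with 320 regions at 2 libraries and 131 at 3. limma on those recovered values called 0 regions at an adjusted p of 0.05 and 73 at an unadjusted p under 0.05, all of them higher at 24 h. The authors' test gave 453 and 10 at the FDR, and 511 higher and 19 lower at an unadjusted p under 0.05. Of the 1385 tested regions, 1172 were higher at 24 h in the authors' deposited table. After scaling to the same median of tested regions 692 were higher. That scaling fixes this count by construction, so it cannot tell whether the direction depends on scaling. The number of tested regions higher at 24 h did depend on 1 library. Of the 1368 with a recovered make-up, 1055 were higher and 200 lower, and 706 and 440 without the 24 h library with the most signal. The 453 increased regions stayed higher under that scaling, and the 451 with a recovered make-up stayed higher without that library, with no test of either.

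**Figure D1:**
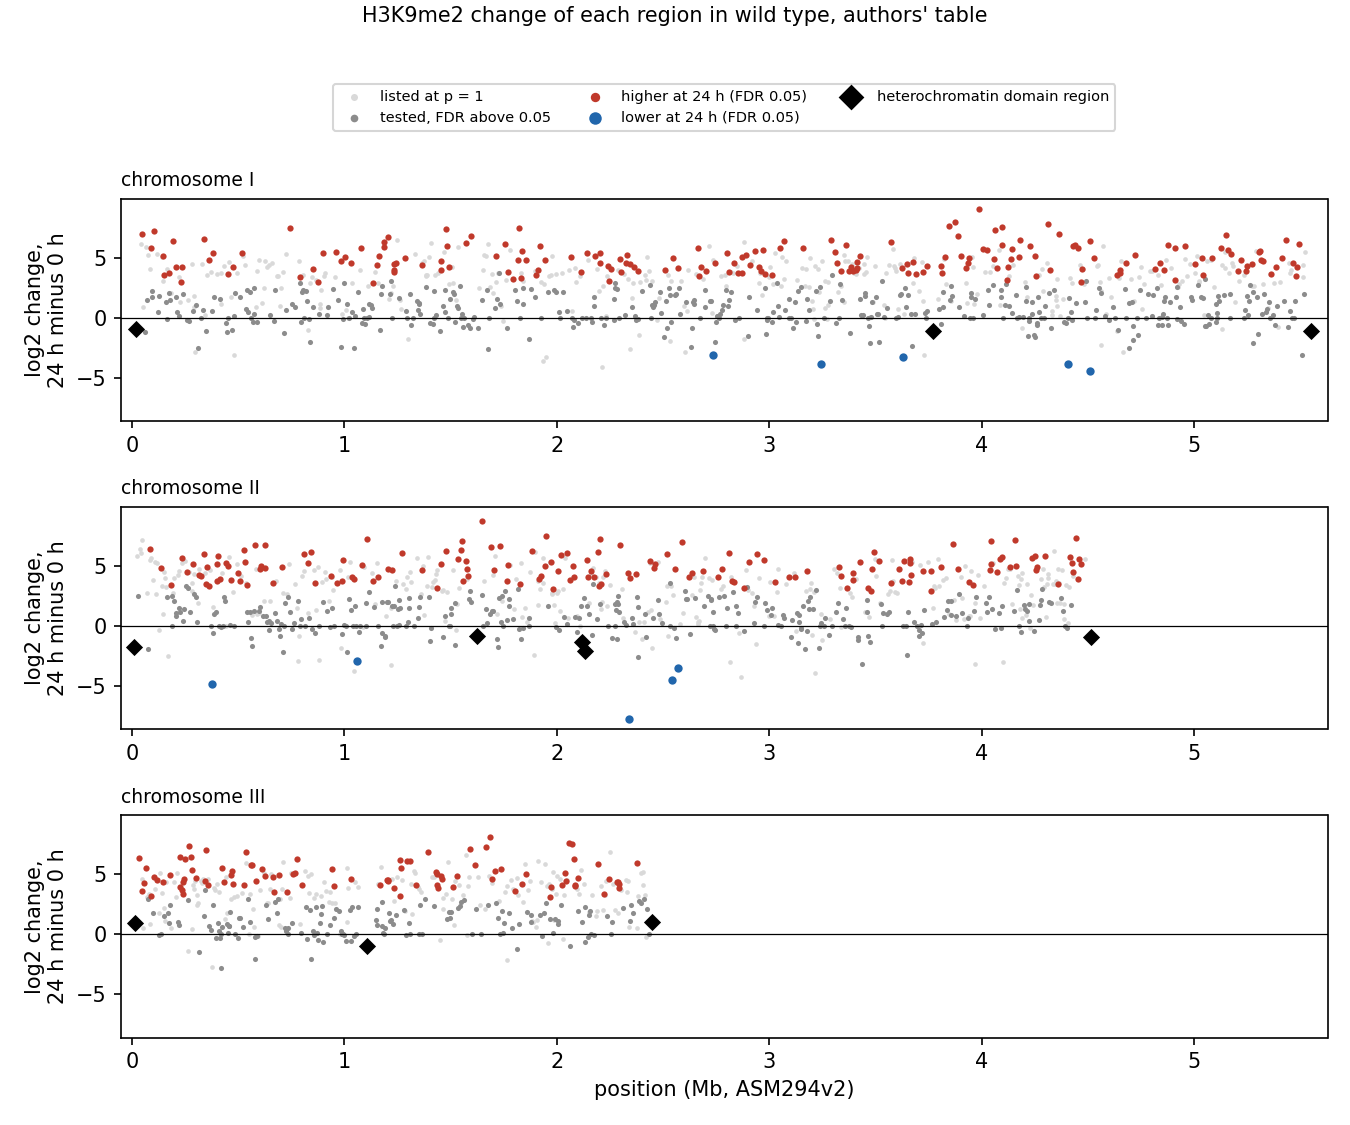
Log2 change in H3K9me2 (24 h minus 0 h, y axis) of each region against its position in Mb (x axis) on the 3 chromosomes, from the authors' deposited table; each point is 1 region, coloured by its FDR and direction, and diamonds mark the widest regions at heterochromatin. Increased regions, 193, 163 and 95 on chromosomes I, II and III, lie along all chromosome arms, and the 10 decreased regions lie on chromosomes I and II.

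The largest increase in the authors' deposited table lay at chromosome I 3982702 to 3991114 (build ASM294v2), a region of 8413 bp over pfl2, which encodes a cell-surface glycoprotein of the flocculin family, and the uncharacterised genes SPOM_SPAPB18E9.04C and SPOM_SPAPB18E9.05C. It had a mean of 425 normalised reads at 24 h and was at least 184-fold higher than at 0 h (FDR = 6.49e-06). The region with the smallest p lay at chromosome II 1645479 to 1647041, over 4 tRNA genes and 881 bp from the edge of the centromere II domain. It stood at 347 normalised reads at 24 h in the authors' deposited table and was at least 150-fold higher (FDR = 4.81e-09). The 8 regions with the next largest changes overlapped protein-coding genes. By the authors' deposited table, tef3, encoding elongation factor 3, rose at least 95.3-fold to 220 normalised reads, pma1 at least 85.7-fold to 198, and the region over tif302, encoding a subunit of initiation factor eIF3, and the endocytosis gene pan1 at least 76.8-fold to 177. The same table gave at least 67.6-fold for pyk1, 65.6-fold for the Hsp70 chaperone gene ssa2, 65.5-fold for tef102, which encodes elongation factor 1A, 63.0-fold for lsd90 and 62.4-fold for the cell wall gene psu1. Of these 10 regions, 8 had signal in 3 of the 5 libraries at 24 h, and those at tef102 and the tRNA genes had no recovered make-up.

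Decreases were few and small in level. The exception was chromosome II 2338887 to 2339918, over the long non-coding RNAs SPOM_SPNCRNA.5604 and SPOM_SPNCRNA.1506 and 495 bp from coa6, which fell from 172 normalised reads to the minimum in the authors' deposited table and was at least 74.1-fold lower at 24 h (FDR = 6.49e-06). The other decreased regions lay over mph1, encoding a spindle checkpoint kinase, psm1, encoding a cohesin subunit, grp1, the splicing and vesicle transport pair prp3 and uso1, nop9, rec8, swi2, SPOM_SPAC6F6.04C and esf1. In the authors' deposited table their 0 h means ran from 24.8 normalised reads at psm1 to 7.37 at esf1, and mph1 was at least 9.82-fold lower at 24 h (FDR = 0.00506). These 9 regions had signal in the same 2 of the 5 libraries assumed at 0 h, and the region near coa6 had no recovered make-up. The 10 decreased regions had a lower mean log2 level over both groups than the 453 increased ones, 3.05 (SD 1.33, n = 10) against 3.78 (SD 1.13, n = 453; permutation test, two-sided, p = 0.0321, adjusted p = 0.0428 over 4 tests). Their mean width, 1138 bp (SD 582), was not detectably different from the 1507 bp (SD 1221) of the increased regions (permutation p = 0.32).

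**Figure D2:**
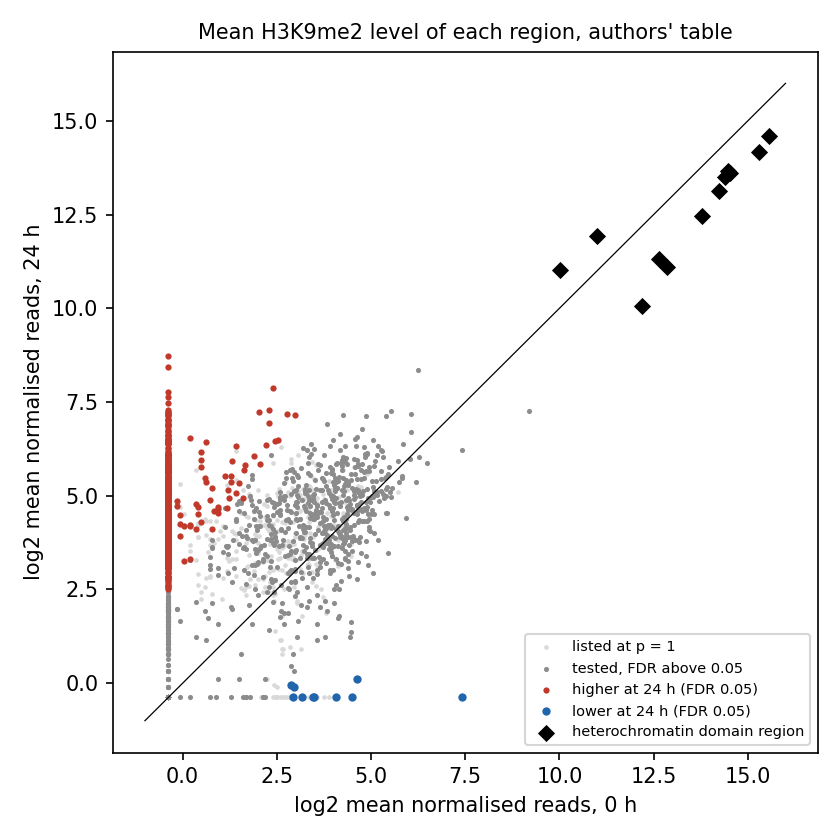
Mean H3K9me2 level of each region at 24 h (y axis) against 0 h (x axis), both as log2 normalised reads from the authors' deposited table; the line marks equal values and diamonds mark the widest regions at heterochromatin. Most increased regions sit on the left edge, the 400 at the 0 h minimum, and the diamonds at the centromeres, mating type and the ends of chromosomes I and II lie below the line.

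The constitutive heterochromatin domains had the highest H3K9me2 levels in the authors' deposited table at both times, and none of their changes, in either direction, passed the FDR of 0.05. The widest region, over centromere III at 1068073 to 1143844, went from 48464 to 24957 normalised reads in the authors' deposited table, a log2 change of -0.96 (FDR = 0.224). Centromere I had a log2 change of -1.11 (FDR = 0.594) and centromere II of -0.82 (FDR = 0.503) in the authors' deposited table. The mating-type locus gave -1.33 (FDR = 0.331) on the chromosome II sequence and -1.33 (FDR = 0.216) on the separate mating-type contig, and the neighbouring region at 2128883 to 2136875 gave -2.11 (FDR = 0.101), by the authors' deposited table. The ends of chromosomes I and II ran from -0.91 to -1.74 in the authors' deposited table, with the smallest FDR, 0.176, at the right end of chromosome I. The ends of chromosome III, on the side of the ribosomal DNA, gave 0.92 (FDR = 0.884) and 1.00 (FDR = 0.867) in the same table.

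Of 11 domains, the widest region of each window and the mating-type contig, 9 were lower at 24 h, with a median log2 change of -0.96, and they held 91.6% of all normalised reads at 0 h and 67.9% at 24 h. Scaling both groups to the same total left 9 of 11 lower with a median of -0.42. Scaling to the same median of tested regions, a shift of 1.72 on the log2 scale, made all 11 lower, which turned the direction at both ends of chromosome III. Over all 28 regions in the windows fixed beforehand, the mean log2 change was 2.15 against 2.42 for the 2164 regions elsewhere (permutation test, two-sided, p = 0.536). Telomere windows of 20 kb gave a difference of -1.53 (p = 0.00244), those of 100 kb gave 0.48 (p = 0.116), and the 11 widest regions alone gave -3.19 (p = 2e-05, the smallest these permutations can give). Regions are not independent replicates, so these p-values describe the table and not the spread between cultures. Level enters these differences too. At 0 h 1154 of the 2192 regions stood at the minimum and could not fall, while the 11 domains stood far above it.

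Within 10 kb of the domain edges, 4 of 19 tested regions rose, against 447 of 1352 farther away (Fisher's exact test, two-sided, p = 0.332). The windows held 3 increased regions of 21 tested, against 450 of 1364 elsewhere (Fisher's exact test, p = 0.0984). The outcome of Fisher's exact test changed with the window: 2 of 19 (p = 0.0466) with 20 kb at the telomeres, 12 of 37 (p = 1) with 100 kb, and 0 of 11 (p = 0.0201) for the widest regions alone. The 3 increased regions in the windows fixed beforehand, named after their values were seen, were the tRNA genes beside centromere II, chromosome I 44701 to 47789 and chromosome III 29986 to 38665. Their log2 changes were 8.82, 6.98 and 6.33 in the authors' deposited table. All 3 stood at the 0 h minimum, so these values are against 0.77 normalised reads and exceed the lower bounds used for folds.

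Glycolysis was the gene group most often found under increased regions. Of its 15 listed enzymes, 12 lay under a region that rose, 1 lay under a tested region that did not pass, 1 lay under a region listed without a p below 1 and 1 lay under no region. The authors' deposited table gave lower bounds of 67.6-fold for pyk1, 52.7-fold for the enolase gene eno101, 50.9-fold for the pyruvate decarboxylase gene pdc101, 49.4-fold for pgk1 and 45.9-fold for adh1. The share of 80% (exact binomial 95% interval 51.9% to 95.7%) compared with 10.3% of the other 5098 protein-coding genes (Fisher's exact test, two-sided, adjusted p = 4.68e-09 over 18 lists) and with genes under tested regions (adjusted p = 8.19e-05). Adjusted over the list alone, 12 members passed. Signal came from 3 libraries of 5 for 8 members and from 2 libraries for 4. Genes share these libraries and are not independent replicates. The p-values of this and the following lists therefore describe the table and not the spread between libraries.

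Genes of the translation machinery were the largest group. Among 131 ribosomal protein genes, 46 lay under increased regions, 21 under tested regions that did not pass and 0 under decreased regions. Examples in the authors' deposited table were rpl1701, at least 33.5-fold higher, rpl301, at least 24.4-fold, and rpl8, at least 22.6-fold. The share was 35.1% (27.0% to 43.9%) against 9.82% of other protein-coding genes (adjusted p = 2.73e-13) and it held against genes under tested regions (adjusted p = 7.6e-09). Many ribosomal protein genes have a near-identical copy, so the copy a read came from is uncertain. Adjusted over the list alone, 47 members passed; signal came from 2 libraries for 36 of the 46 and from 3 for 10. Translation factors followed the same direction, with 12 of 34 under increased regions (adjusted p = 0.000432 against other protein-coding genes; 12 adjusted over the list alone). Against genes under tested regions the translation factors did not pass (adjusted p = 0.173). The elongation factor 1A genes tef101, tef102 and tef103 are near-identical copies and are uncertain in the same way. Of the 12, 8 had signal in 3 libraries, 3 in 2 libraries and 1 had no recovered make-up.

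Chaperone and stress genes rose as well. Of 19 listed genes, 11 lay under increased regions, 4 under tested regions that did not pass and 0 under decreased ones. The authors' deposited table placed ssa2 at least 65.6-fold higher, the ribosome-associated chaperone gene sks2 at least 51.4-fold, hsp90 at least 38.8-fold and the mitochondrial chaperonin gene mcp60 at least 31.8-fold. The list passed against other protein-coding genes (57.9% against 10.3%, adjusted p = 3.09e-06) and against genes under tested regions (adjusted p = 0.00667). Adjusted over the list alone, 12 members passed; 8 of the 11 had signal in 3 libraries and 3 in 2 libraries.

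Genes that respond to nitrogen starvation were a further group with increases. Of 27 members, 10 lay under increased regions and 8 under tested regions that did not pass. By the authors' deposited table, the ammonium transporter gene amt1 rose at least 61.5-fold, the GATA transcription factor gene gaf1 at least 51.4-fold, the oligopeptide transporter gene isp4 at least 45.4-fold and the glutamine synthetase gene gln1 at least 37.7-fold. The region over isp6, which encodes a vacuolar protease, was already above the minimum at 0 h and had a log2 change of 5.01 (FDR = 0.00846) in the authors' deposited table. The list passed against other protein-coding genes (37.0% against 10.3%, adjusted p = 0.000843) and not against genes under tested regions (adjusted p = 0.0919). Adjusted over the list alone, 10 members passed; 5 had signal in 3 libraries and 5 in 2 libraries.

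Nutrient transport lists showed smaller counts, 6 of 20 genes under increased regions for iron and phosphate uptake and 6 of 18 for sugar transport and hexose use. In the authors' deposited table the neighbouring phosphate genes pho84 and pho1 shared 1 region, at least 54.3-fold higher, and the siderophore transporter gene str3 was at least 18.7-fold higher. The hexose transporter gene ght8 was at least 29.8-fold higher, the hexokinase gene hxk2 at least 18.7-fold and the maltase gene agl1 at least 16.7-fold, by the authors' deposited table; 1 of the 6 sugar members, zym1, encodes a metallothionein and not a sugar enzyme. Against other protein-coding genes the adjusted p was 0.0309 for iron and phosphate and 0.0203 for sugars, and 6 members of each passed when adjusted over the list alone. Neither list passed against genes under tested regions (adjusted p = 0.206 and 0.0919) or with gene bodies extended by 500 bp (adjusted p = 0.0846 and 0.0658). The iron and phosphate list also missed the threshold when at least 50% of the region had to overlap (4 of 20, adjusted p = 0.210), and the sugar list at an FDR of 0.01 (4 of 18, adjusted p = 0.0763). Signal came from 3 libraries for 3 iron and phosphate members and 2 sugar members.

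**Figure D3:**
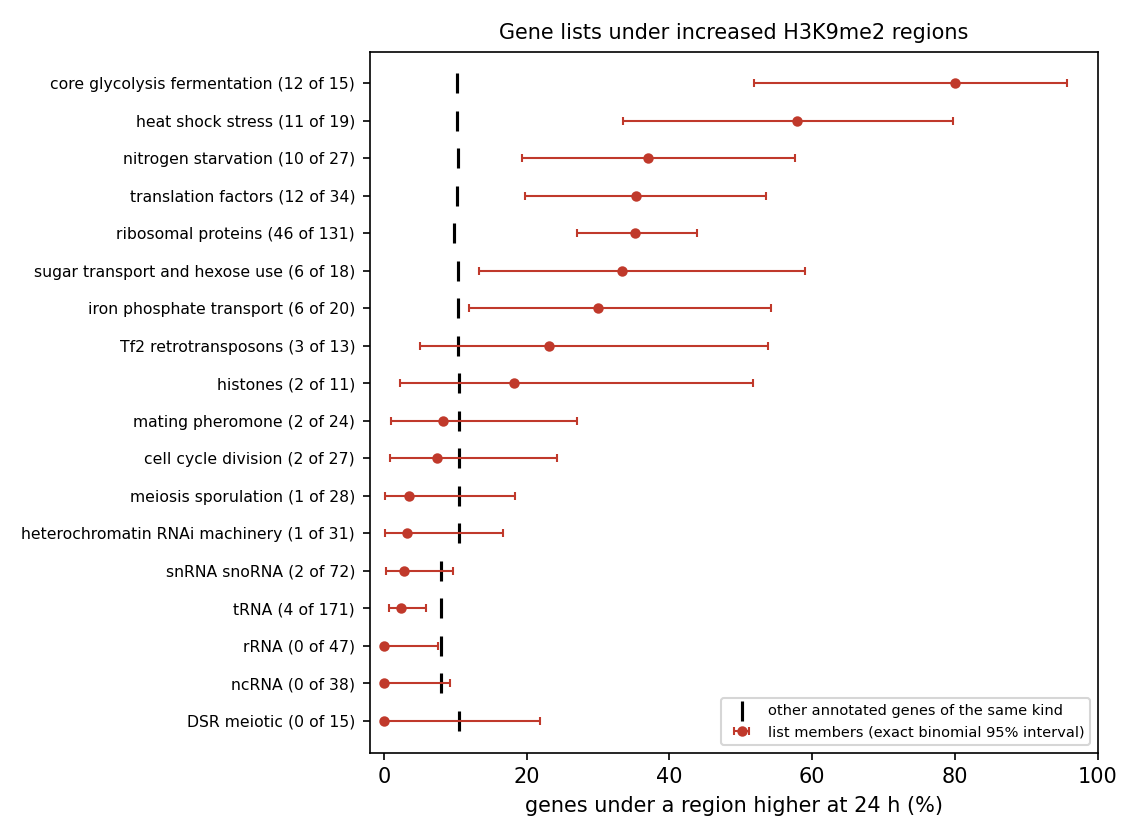
Share of the members of each gene list that lay under a region higher at 24 h (x axis, percent), with exact binomial 95% intervals; counts of increased members and list sizes stand beside the list names, and the vertical ticks give the share among other annotated genes of the same kind. Glycolysis (80%), stress (57.9%) and nitrogen starvation (37.0%) have the highest shares, and no ribosomal RNA gene (0 of 47) lay under an increased region.

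Gene groups tied to sexual differentiation and to the silencing machinery were not enriched. In the list of meiotic genes whose transcripts are removed in growing cells through their DSR (determinant of selective removal) motifs, 0 of 15 lay under increased regions (adjusted p = 0.441) and rec8, encoding the meiotic cohesin subunit, lay under a decreased one, from 8.98 normalised reads to the minimum in the authors' deposited table (FDR = 0.0214). The wider meiosis and sporulation list had 1 of 28 members increased, mei2, which was at least 28.9-fold higher in the authors' deposited table. Mating and pheromone genes had 2 of 24, map3 and ste7, at least 8.14-fold and 4.14-fold higher in the authors' deposited table, with the map3 region also over his6. Cell cycle genes had 2 of 27, the ribonucleotide reductase gene cdc22 at least 21.7-fold and srw1 at least 7.98-fold higher. Among 31 genes of heterochromatin and RNA interference, 1 rose, the transcription factor gene atf1, at least 27.4-fold higher in the authors' deposited table. Of the 11 histone genes, hht2 and hhf2 shared 1 increased region, at least 8.52-fold higher in the authors' deposited table. The adjusted p of these lists against other protein-coding genes ranged from 0.343 to 1, apart from the value already given for DSR genes. Signal at each of these increased members came from 2 libraries of 5, and from 3 at atf1. Adjusted over the list alone the counts were 0 for DSR genes, 1 for meiosis, 2 for mating, 2 for the cell cycle, 1 for heterochromatin and 3 for histones.

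Non-coding genes and retrotransposons gave mixed counts. The Tf2 retrotransposons Tf2-4, Tf2-11 and Tf2-6 rose at least 22.4-fold, 17.8-fold and 16.7-fold in the authors' deposited table, 3 of 13 copies (adjusted p = 0.222; 3 adjusted over the list alone), each from 2 libraries. These copies are nearly identical in sequence, so which copy the reads came from is uncertain. Of 171 tRNA genes, 4 lay under an increased region, all in the region beside centromere II, which is fewer than among other annotated genes (2.34% against 8.01%, adjusted p = 0.0115). This did not hold with gene bodies extended by 500 bp (11 tRNA genes, adjusted p = 0.0658) or at an FDR of 0.01 (4, adjusted p = 0.157), and the adjusted p ranged from 0.000194 to 0.157 over the alternatives. tRNA genes are short, with a median of 73 bp, and were not compared with genes of matched length. No rRNA gene (0 of 47, adjusted p = 0.101) and no gene of the remaining ncRNA class (0 of 38, adjusted p = 0.128) lay under an increased region. The snRNA and snoRNA genes had 2 of 72 (adjusted p = 0.204), snR30 and snu32, at least 5.20-fold and 3.62-fold higher in the authors' deposited table. Adjusted over the list alone the counts were 4 for tRNA, 0 for rRNA, 0 for ncRNA and 2 for snRNA and snoRNA.

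The increased regions fell inside protein-coding genes. Outside the windows, 97.8% of the bases of 448 increased regions lay in protein-coding gene bodies, above all 1000 circular shifts of the regions along the chromosomes, whose mean was 76.7%. The 903 tested regions that did not pass had a similar share, 98.8%, against a mean of 76.8% in shifts. In all, 535 protein-coding genes, 457 long non-coding RNA genes, 4 tRNA genes, 2 snoRNA genes and 2 pseudogenes overlapped an increased region, and 10 protein-coding genes overlapped a decreased one. On average, the increased regions were narrower than the 904 tested regions outside the windows that did not pass, 1507 bp (SD 1221) against 1717 bp (SD 1120; permutation test, two-sided, p = 0.00138, adjusted p = 0.00276).

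**Figure D4:**
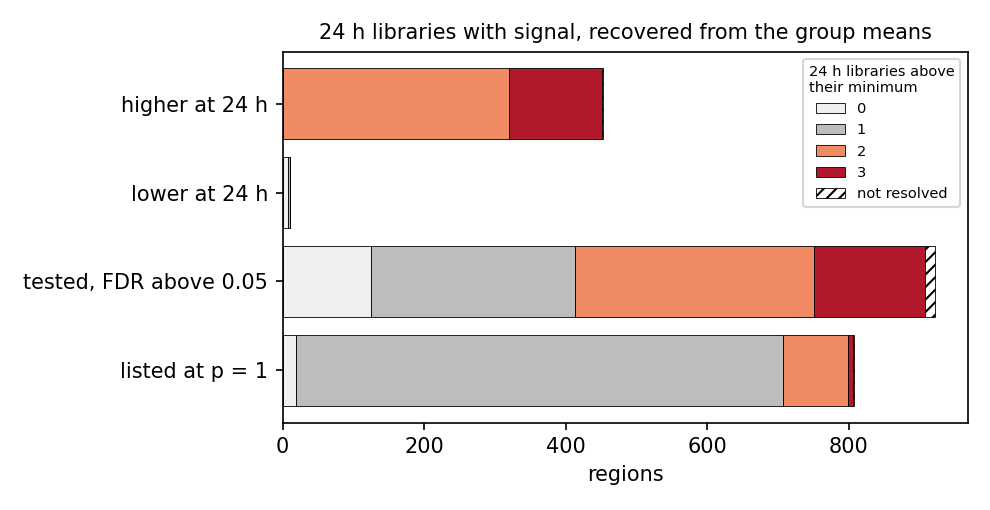
Number of regions (x axis) by the number of 24 h libraries with signal above their minimum, as recovered from the authors' group means, for each class of region (y axis); colours give 0, 1, 2 or 3 libraries and hatching marks regions with no recovered make-up. Increased regions had 2 (320) or 3 (131) such libraries, and 688 of the regions with a listed p of 1 had exactly 1.

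The libraries behind the increases were uneven. Of the 451 increased regions with a recovered make-up, 450 had signal in the 24 h library called A here, 440 in library B and 143 in library C, and these gave 58.1%, 33.4% and 8.50% of the recovered 24 h signal in those regions. The letters only name recovered libraries, since nothing in the tables ties them to a replicate number. With 5 libraries per group, as assumed for the recovery, the exact permutation test of 5 against 5 gives a smallest p of 0.00794, and the recovered values gave 0.167 to 0.444 per increased region, as at least 2 libraries of 24 h stood at their minimum in each. Without library A, 132 of the 451 regions kept signal in at least 2 libraries of 24 h, and without library B 142. The shorter of the deposited sheets held 453 regions, and all 453 were the increased regions of the full sheet with the same log2 values (within 1e-12).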

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

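Tests of single libraries, of background correction, of regions at both minima and of low reads were chosen or changed after the result was seen, and the GC-matched lists were added after the first GC comparison had pointed to GC. Among the 807 regions listed with a p of 1, which took no part in the authors' adjustment, 788 had a 24 h mean above the minimum in the authors' deposited table. On a contig outside the 3 chromosomes, 2 of 4 regions passed the FDR of 0.05 in the authors' deposited table, at 11879 to 13315 and at 14162 to 15383, at least 17.1-fold and 14.1-fold higher at 24 h.

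The regions with a p of 1 differed from the rest in how many libraries carried them. Exactly 1 of the 24 h libraries was above its minimum in 85.4% of the 806 such regions with a recovered make-up, against 21.3% of 1369 other regions, so a candidate explanation is that a test that sets aside outlying counts gave no p there. The tables argue against a loss of the regions with the fewest reads, since all 113 regions at the minimum in both groups had a p below 1. Low reads stay open. In 10 classes of the mean over both groups, the share of regions with a p of 1 was 0% in the lowest, 61.6% in the next and 9.09% in the highest, which goes with low reads except at the lowest values. The median 24 h mean was 13.2 normalised reads, against 13.6 in tested regions that did not pass (permutation test of medians, p = 0.521), which the first form of this test, without a p, had counted in favour of low reads. The mean log2 level at 24 h was higher in the regions with a p of 1, 3.68 (SD 1.17) against 3.34 (SD 2.30; permutation p = 0.00014), but not without the regions at the 24 h minimum, 3.78 against 3.92 (788 and 797 regions, p = 0.0725). No biological explanation was tested.

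The increases at 24 h rested on 2 or 3 of the 5 libraries assumed per group. Unrelated noise could not be excluded. Libraries A and B correlated over the 2174 resolved regions (Spearman's rho 0.377 across regions, which are not independent replicates). The 2 libraries with signal at 0 h correlated more strongly (0.577). Region width was not controlled, and background reads alone can correlate through it. Missing background correction of the 0 h libraries is argued against by 53.0% of resolved regions with both at their minimum. Library A was above its minimum in 1998 of 2175 regions, so missing correction may still hold for it. Chance in the grouping could not be excluded: limma called 0 regions in the real split (73 at an unadjusted p under 0.05, against the authors' 453 and 10), a count that all 100 splits reach by construction, and at an unadjusted p under 0.05 33 of 100 splits gave as many. The highest other split called 345 regions, and it set the 5 libraries with signal against the 5 entered as 0, so this count follows from the recovery and shows no structure of the samples beyond it. A biological difference between cultures stays open and untested.

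The increased regions lay over genes with strongly biased codons, a proxy of high expression in growing cells. A signal that follows expression level would go with the codon adaptation percentiles. The median was 78.3 in 488 genes under increased regions, ribosomal protein genes left out. It was 55.8 in 1112 genes under tested regions that did not pass (permutation test of means, p = 2e-05, the smallest these permutations can give). Growing cells are the 0 h state, however, where 400 of the 453 increased regions stood at the minimum. The percentiles met the prediction for a signal that follows expression level, which was written before the result was seen. Being fixed for each gene, they cannot tell why levels rose at 24 h, and expression at 24 h was not examined. Gene length is argued against, since 0 of 10000 length-matched lists reached the increased members of the ribosomal protein or the glycolysis list. Of 10000 GC-matched lists, 336 reached the first and 2 the second, fewer than predicted for GC content as the whole cause. Matching was within 10 classes of GC, so differences inside a class remain and GC as the whole cause is not excluded. GC content may account for much of the excess of increased members. GC-matched lists held on average 37.2 increased members against the 46 ribosomal protein genes (35.6 when drawn from other genes), where length-matched lists held 9.83, and 4.84 against the 12 of glycolysis. Among genes with GC at or below the median, the median percentile was 46.9 under increased regions and 43.9 under tested regions that did not pass, so that most of the difference between 78.3 and 55.8 was absent there. Within 10 classes of GC content a mean difference of 8.85 remained of 14.2. Methylation of transcribed genes and unspecific recovery of transcribed chromatin both stay open, with the clr4D libraries and inputs not analysed here.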

How the results depend on the processing

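Tests with limma, without single libraries (the direction of tested regions among them, and the count of libraries and the bound of 2.31 after a first measure by fold against the minimum had not moved), with all listed regions adjusted, with the widest regions and with genes under tested regions were chosen after the data were seen. An FDR of 0.01 left 296 changed regions, 293 higher and 3 lower, and a share of 99.0% higher. A minimum mean of 10 with a new adjustment left 277, of which 274 were higher and 3 lower; fewer regions pass by construction, as low regions are removed. limma on the recovered values called 0 changed regions, 0 higher and 0 lower (73 at an unadjusted p under 0.05, and 453 and 10 by the authors' test), and so did the same fit with a pseudocount of 0.5 or 5 (83 and 59 unadjusted) or without any 1 of the libraries with signal or 1 without signal per group (2, without C, to 112, without a 24 h library lacking signal); the cause was not tested. Leaving out 1 of the recovered 24 h libraries left 132 (without A), 142 (without B) and 439 (without C) of 451 increased regions with signal in at least 2 libraries, and 383, 438 and 449 at least 2-fold above the larger of the 0 h mean and 2.31 normalised reads. The difference inside minus outside the heterochromatin windows, -0.27, became 0.48 with 100 kb telomere windows, -1.53 with 20 kb windows and -3.19 for the widest regions; the narrower windows drop arm regions by construction. The number of enriched lists, 7, fell to 3 against genes under tested regions, and was 5 to 7 otherwise. A minimum fold, merging, adjustment over all listed regions (432 changed) and the sheet overlap left the counts close to those reported. Leaving out library A changed the tested regions higher at 24 h from 1055 to 706 of 1368. Among single lists, window counts and this direction, 87 alternatives gave the same call, 11 a weaker and 1 a stronger one. The same call includes lists that passed in no setting and the drop to 706. Among the alternatives for the main results, 20 gave the same call and 39 a weaker one. A further 2 gave a stronger, 1 a reversed and 1 a moved one. No paired analysis was possible because the tables hold 1 mean per group and the recovered libraries carry no replicate number; fits without a numbered replicate and strain comparisons were not run. Count models (DESeq2, and edgeR with TMM, total-count scaling or filterByExpr) were tried on the recovered counts after the other results were seen. They are left out because the design fixed beforehand kept count models for deposited counts per library, and the deposited columns are log2 group means. With the table's scaling and all libraries, DESeq2 gave numbers of calls close to the authors'. These calls were not stable: the number and direction varied with the size factors and with library A. Many other splits of the libraries gave as many, and edgeR made no call after adjustment. These fits are described without values, and no result here rests on them. Depth limits the low regions, where a mean near 0.77 is the minimum of the table.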

Other observations

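Product names gave further themes among the 1682 protein-coding genes under tested regions, of which 31.8% lay under increased regions. Of 32 product words carried by at least 20 such genes, generic words such as protein and subunit left out, 5 passed Fisher's exact test after Benjamini-Hochberg adjustment. Increased shares were higher for ribosomal (49 of 86 genes, adjusted p = 1.76e-05), phosphate (13 of 20, adjusted p = 0.0282), dehydrogenase (24 of 46, adjusted p = 0.0295) and transporter (32 of 67, adjusted p = 0.0442). The share was lower for complex (21 of 155, or 13.5%, adjusted p = 2e-06), a word found in the names of subunits of many assemblies. The words were searched after the data were seen.

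The share of genes under increased regions rose with codon adaptation mainly at its top. In 5 classes of 1019 protein-coding genes each, ordered from low to high codon adaptation, it was 4.81%, 5.40%, 6.67%, 8.24% and 27.3%. These classes include the ribosomal protein genes, which define the index and stand at its top by construction; without them the share in the highest class was 26.0% (232 of 892). Within 10 classes of GC content the mean codon adaptation percentile of genes under increased regions remained 8.85 above that of genes under tested regions that did not pass (14.2 without regard to GC, ribosomal protein genes left out of both; stratified permutation p = 0.0001, the smallest 10000 permutations can give).

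Of 26 listed regions within 10 kb of a heterochromatin domain, 7 were listed without a p below 1. Past the threshold were 4, namely the tRNA genes beside centromere II, chromosome I 44701 to 47789, chromosome III 29986 to 38665 and chromosome I 3744302 to 3744826, the last with a log2 change of 4.31 in the authors' deposited table (FDR = 0.00868).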
